A study of Mus musculus with 4 samples.

How the data were processed

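Single-cell RNA sequencing libraries from the kidneys of 4 wild-type mice were analysed. Per the labels, every mouse had undergone contrast-induced acute kidney injury (CIAKI), a loss of kidney function that follows an iodinated contrast agent, and the 4 libraries are biological replicates of 1 group. The labels assign all 4 to batch 1, although mouse 4 shared 1 cell barcode with the other libraries where 133 were expected. No control mice are among the samples analysed here, so every test compared cell classes inside injured kidneys and none measured the effect of contrast. The contrast agent, its dose and the time of collection were not given in the sources used here.

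The values used were counts of unique molecular identifiers (UMIs) per gene and cell barcode, deposited as 1 sparse matrix per library. Per the file headers, the matrices were made with Cell Ranger 9.0.1. The submitters' processing notes name the same tool and Seurat 4.1.1, with no role stated for the latter. Each matrix held whole-number counts for 57132 genes, and every barcode in it had 500 UMIs or more. The genome build, the annotation and the aligner settings were not given in the sources used here, and no coordinates are reported. Gene symbols were taken from the files. Of the gene identifiers, 51880 matched the reference table of names, and 7 symbols of the gene lists were matched through their identifier.

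The deposited matrices held 48213 barcodes and 273788487 UMIs. Barcodes were kept with 500 UMIs or more, 300 genes or more and a mitochondrial share under 50%, which left 40939. Doublets were called per library with the Scrublet method in scanpy 1.11.5 and left out. The caller marked 139 barcodes, of which 131 were in mouse 2. In mice 1, 3 and 4 it marked 0.0282%, 0.0232% and 0.0248% of cells, which shows that it did not work there. Clusters with markers of unrelated classes were therefore left unnamed, and an alternative removed the highest doublet scores of every library (0.8% per 1000 cells). In all, 40800 cells were kept. Total counts per gene differed between every pair of libraries beyond sampling noise (chi-square per degree of freedom 179 or more), so none was merged with another as a repeat deposit. That the libraries came from separate mice rests on the labels.

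Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen without the response lists, mitochondrial and ribosomal genes, gave 30 principal components, a graph of 15 exact nearest neighbours and a Leiden partition (leidenalg 0.10.2) at resolution 1, with no integration across libraries. This gave 50 clusters. A cluster was called "-like" a cell type when at least 3 fixed markers of that type each had UMIs in 20% of its cells or more and lay at least 2-fold above the other cells. The markers of 18 cell types, the clustering resolution, the gene lists, the filters and the comparisons of cell classes with their tests were fixed before the data were examined. The numerical thresholds of naming were set afterwards, as were most tests of explanations. A cluster stayed unnamed when it had too few markers, when it held markers of an unrelated type or a high doublet score, or when its leading genes held more markers of a type of another lineage. Where they held more fixed markers of a related type, as in some clusters of the alternatives but in no named cluster of the reported setting, the name was kept. Cluster 9, named T lymphocyte-like, held 1 fixed marker of each of 2 related types among its 10 leading genes, Il7r of T lymphocytes and Klrb1c of NK cells. In all, 16 clusters with 5064 cells stayed unnamed.

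Cluster 32 met the marker rule for injured proximal tubule with Sox9, Sox4, Dcdc2a, Spp1 and Krt8. The rule for this name also asked for 2 or more markers of the proximal tubule segments at the same limits, which the cluster met. Its leading genes included Ncam1 and Cldn1, known from the epithelium that lines the glomerular capsule. It was left without a cell type name after the data and a first fit had been seen, and is called the injured-marker cluster. The rule for this asked for 3 or more genes of the capsule epithelium at 2-fold or more above the other cells. These genes were chosen after the clusters were seen. The planned comparison of injured with other proximal tubule cells is reported for this cluster by number. No cluster earned the name of the straight proximal segment (S3) or of erythroid cells, so the planned comparison of S3 with S1/S2 was not run. All proximal tubule-like clusters were named by S1/S2 markers, which does not exclude S3 cells in them. With a mitochondrial limit of 20%, 1 such cluster, mostly of mouse 3, had more S3 than S1/S2 markers among its 10 leading genes.

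For each comparison, raw counts were summed per mouse and cell class and tested across mice with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3, with the mouse as a block. Both classes of a comparison came from the same 4 animals. Deviations from the class means correlated between the classes of each mouse (r from 0.427 to 0.808, across genes, which are not independent replicates). For mice 1 and 2 the highest r with another mouse, 0.328 to 0.434, came near their own 0.427 to 0.573. For mice 3 and 4 it was -0.420 to -0.109, so only these 2 stood clearly apart. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of 1 or more. All adjusted p-values of genes come from this edgeR fit. CPM values beside these tests are TMM-scaled, while those given for injury transcripts and for Umod and S100a9 are plain. Simulated counts with 200 changed genes tested the procedure. Here a gene counted as called at an adjusted p under 0.05 alone, without the fold limit of the reported calls. The simulation held no mean differences between mice, so its shares are not those of the full calling rule on the real data. In proximal tubule-like against thick ascending limb-like cells (11871 genes), 52% of 2-fold and 99% of 4-fold changes were recovered, and 6.79% of calls were false. The values were 51%, 95% and 6.41% for the injured-marker cluster against proximal tubule-like cells (10871 genes). They were 10%, 85% and 4.04% for macrophage-like against endothelial-like cells (12952 genes).

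The response lists hold 278 genes in 23 groups: tubular injury, NRF2 targets, antioxidant enzymes, ferroptosis, heat shock, unfolded protein response, hypoxia response, p53 targets, cell death effectors, cell cycle, immediate early genes, inflammatory mediators, interferon response, MHC class I, MHC class II, complement, matrix and TGF-beta, vasoactive mediators and receptors, endocytosis, gluconeogenesis, fatty acid oxidation, oxidative phosphorylation, and glycolysis. Each list was counted by members called higher or lower, adjusted over all genes and over the list alone. It was also tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg adjustment over 23 lists). With a correlation estimated from the data, 0 of 4, 0 of 13 and 0 of 2 camera calls held in the 3 comparisons. These estimates rest on few residual degrees of freedom.

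Genes were named by a rule. From each list it took the 2 called members with the highest and the 2 with the lowest log2 fold change. It added the 6 highest and 6 lowest called genes with the same direction in 4 of 4 mice and 100 CPM or more in the higher class, leaving out clustering features, markers, mitochondrial and ribosomal genes and unnamed models. For injury transcripts per class the genes were Havcr1, Lcn2, Krt20, Vcam1, Spp1, Clu, Sox9, Cdkn1a, Hmox1 and Ccl2. Any other gene named was chosen after its values were seen. Some genes taken by the rule are not reported here.

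Shares are means over mice with SD, and single-mouse shares carry exact Clopper-Pearson 95% intervals that cover counting error only. A share of 0 carries instead the limit that 3 counts of the total give. Immune and tubular shares were compared with a two-sided exact sign permutation over mice, which with 4 mice cannot give a p below 0.125. Alternatives were DESeq2 1.42.0, its size factors, no low-count filter, no mouse block, thinning to 1000 UMIs per cell, doublets kept, a mitochondrial limit of 20%, a minimum of 1000 UMIs, resolution 0.5, centring within library, and each mouse left out. After the data were seen, 3 more were added: the highest doublet scores out, ribosomal RNA genes out, and the injured-marker cluster counted as proximal tubule-like. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0 was used.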

Results

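The study profiled renal cell composition and the transcripts of each renal cell class after contrast-induced acute kidney injury. Kidneys of 4 mice were dissociated and 1 droplet library was made from each. Mice 1 to 4 gave 66762741, 64757026, 105436725 and 36831995 UMIs in 8790, 9368, 17312 and 12743 barcodes. After filtering, 7083, 8727, 12901 and 12089 cells remained, with medians of 5549, 5772, 5655 and 2077 UMIs and 2006, 2040, 2273 and 993 genes per cell. Mouse 4 was thus sampled less deeply per cell, and ribosomal protein transcripts took a median 13.7% of its UMIs against 1.48%, 1.51% and 2.35% in mice 1 to 3. The mitochondrial limit removed 18.9%, 4.65%, 25.3% and 3.01% of the barcodes of mice 1 to 4.

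Immune cells made up the largest part of the recovered cells. Neutrophil-like cells, first responders of innate immunity, accounted for 18.5% ± 17.6 (SD, n = 4) of cells, macrophage- and monocyte-like cells for 13.5% ± 5.37 and T lymphocyte-like cells for 10.2% ± 12.1. Endothelial-like cells, which line blood vessels, accounted for 18.2% ± 7.25. Among tubular cells, proximal tubule-like cells, which reabsorb most of the filtrate, accounted for 6.16% ± 3.63 and thick ascending limb-like cells for 5.13% ± 3.19. The immune-like share of 44.9% ± 9.32 lay above the tubular-like share of 17.3% ± 8.76 in 4 of 4 mice, by 27.5 ± 13.1 percentage points (exact sign permutation, two-sided, p = 0.125, the smallest possible with n = 4). The mitochondrial limit can lower the tubular-like share, since the barcodes it removed held proximal tubule S1/S2 markers at 2.74 to 6.74 times and thick ascending limb markers at 1.91 to 5.16 times the level of those under it. It removed 18.9% and 25.3% of the barcodes of mice 1 and 3, but 4.65% and 3.01% of those of mice 2 and 4.

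The neutrophil-like share ranged widely, at 28.2% (95% interval 27.1 to 29.2) in mouse 1, 38.4% (37.4 to 39.4) in mouse 2, 6.04% (5.63 to 6.46) in mouse 3 and 1.55% (1.33 to 1.78) in mouse 4. Its mean was 11.9% without mouse 2. T lymphocyte-like cells made up 28.3% (27.5 to 29.1) of mouse 4, and their mean without it was 4.15%. Fibroblast- and mural-like cells (3.86% ± 4.20) and podocyte-like cells (1.33% ± 1.24) came mostly from mouse 3, and their means without it were 1.79% and 0.721%. Collecting duct and connecting tubule-like cells (2.22% ± 2.82) and dendritic-like cells (1.29% ± 2.24) came mostly from mouse 4, and their means without it were 0.819% and 0.170%. The dendritic-like share depended on naming, since unnamed cluster 29, led by Ccr7, held 420 cells of mouse 3. Among cells of 1000 UMIs or more, a Ccr7-led cluster with 288 cells of mouse 3 was named dendritic-like. So was another with 63 cells of mouse 3. NK-like cells averaged 0.296% ± 0.557, of which mouse 3 held 1.13%, and the mean without mouse 3 was 0.0171%. In mouse 4, 0 of 12089 cells were NK-like, which allows a share of up to 0.0248% for counting error alone. The count also depended on how clusters were drawn and named. Cluster 9, counted as T lymphocyte-like, held 1238 cells of mouse 4 and was led by natural killer receptor genes, and 29 cells of mouse 4 were NK-like among cells of 1000 UMIs or more and 12 with a mitochondrial limit of 20%. The remaining classes were distal convoluted tubule-like (1.82% ± 1.12), intercalated-like (1.54% ± 1.34), B lymphocyte- and plasma-like (1.10% ± 1.09) and thin limb-like cells (0.474% ± 0.110). Without mouse 3 the B lymphocyte- and plasma-like mean was 0.683%, and without mouse 4 the intercalated-like mean was 0.937%. The injured-marker cluster held 0.734%, 0.493%, 1.29% and 0.620% of the cells of mice 1 to 4. Unnamed clusters held 23.3%, 12.7%, 11.1% and 7.19%, which limits how closely shares can be compared between mice. Unnamed cluster 13 held 781 cells of mouse 1 and 272 of mouse 2. It passed 9 macrophage markers but was left out because it also held neutrophil markers. The macrophage-like class counted 537 cells in mouse 1 and 1065 in mouse 2.

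**Figure D1:**
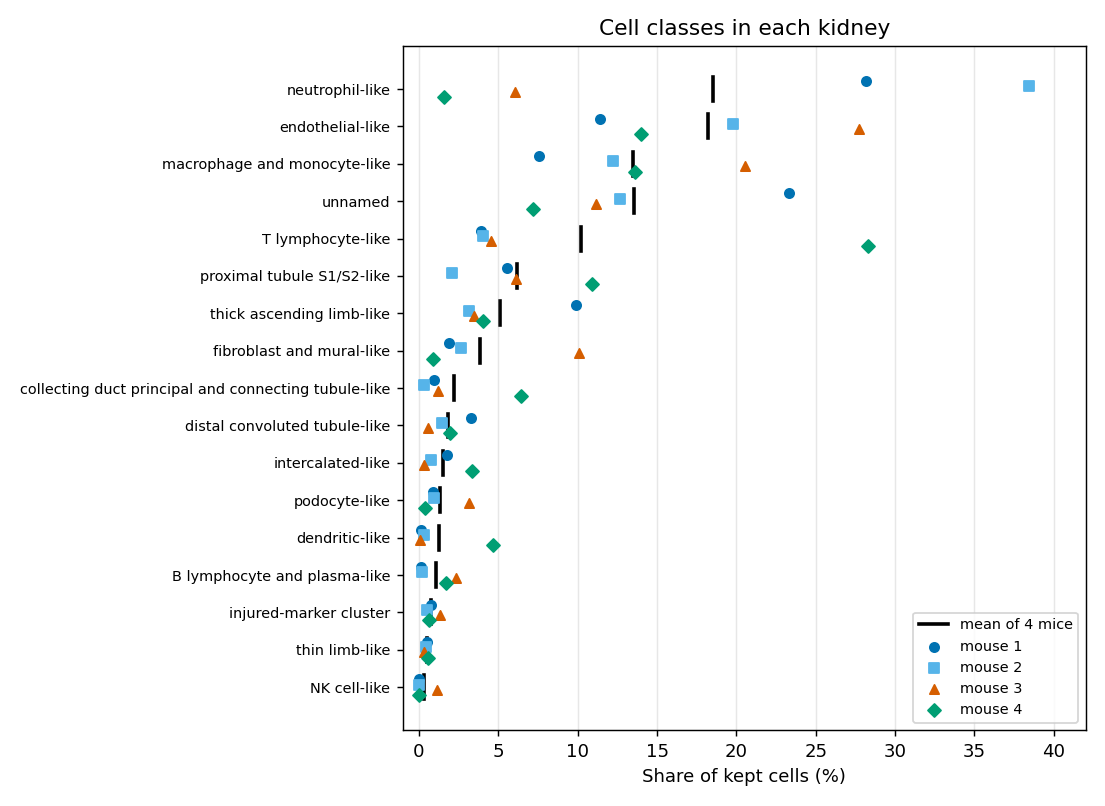
Share of kept cells (%) in each cell class, with 1 point per mouse and a black bar at the mean of 4 mice. Neutrophil-like cells range from 1.55% to 38.4%, and T lymphocyte-like cells stand at 28.3% in mouse 4 against 4.53% or less in the other mice.

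The larger classes were built from different clusters in different mice. Endothelial-like cells came mostly from cluster 3 in mice 1 and 2, from clusters 1, 16 and 31 in mouse 3 and from cluster 4 in mouse 4. Cluster 4 also held 118 and 202 endothelial-like cells of mice 1 and 2, and cluster 40 held 84 and 86. Macrophage-like cells came mostly from cluster 6 in mice 1 and 2, from clusters 7 and 8 in mouse 3 and from cluster 5 in mouse 4. Cluster 7, with 1387 cells, all of mouse 3, was led by Il27, Dnase1l3, Cd40 and Slamf7, genes of activated myeloid cells. It was named by 3 markers, the fewest allowed (C1qb, C1qc and Adgre1). The Il27-led cluster was unnamed with doublets kept, with a mitochondrial limit of 20% and at the lower clustering resolution. Neutrophil-like cells came mostly from cluster 0 in mice 1, 2 and 4 and from cluster 19 in mouse 3, the latter led by the granule protein genes Camp, Ngp and Ltf. T lymphocyte-like cells came mostly from cluster 10 in mice 1 to 3 and from clusters 2 and 9 in mouse 4, and cluster 9 was led by the natural killer receptor genes Klrc1, Klrb1c, Klrk1 and Klrd1. Proximal tubule-like cells came mostly from clusters 14 and 11 in mice 1, 2 and 4 and from clusters 27 and 14 in mouse 3. Cluster 27 was led in part by the fibrinogen genes Fgb, Fga and Fgg.

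Injury transcripts were distributed unevenly over the nephron. Havcr1, which encodes the kidney injury molecule KIM-1, was found in 20.2% ± 14.4 of proximal tubule-like cells at 139 ± 113 CPM (n = 4). In thick ascending limb-like cells it was found in 0.705% ± 1.06, and in neutrophil-like cells, which should lack it, in 0.562% ± 0.751, so the former share was not told apart from background given the spread between mice. The median depths of these classes, averaged over mice, were 3909, 6529 and 5176 UMIs, and thinning all cells to 1000 UMIs gave shares of 8.41%, 0.250% ± 0.330 and 0.0743% ± 0.129. Lcn2, the gene of the urinary injury marker NGAL, showed the opposite distribution, at 5082 ± 4217 CPM in thick ascending limb-like and 499 ± 744 CPM in proximal tubule-like cells. The share of Lcn2-positive cells was 86.8%, 32.5% and 29.97% in thick ascending limb-like, proximal tubule-like and T lymphocyte-like cells, and 68.3%, 16.1% and 12.5% after thinning, with a median depth of 4201 UMIs in the last class. Spp1 (osteopontin) reached 35074 ± 15539 CPM in thick ascending limb-like against 4650 ± 1518 CPM in proximal tubule-like and 272 ± 87.8 CPM in T lymphocyte-like cells. Clu (clusterin) stood at 386 ± 142 CPM in thick ascending limb-like cells. In proximal tubule-like cells it stood at 23.3 ± 18.3 CPM, near the 15.8 ± 7.33 CPM of T lymphocyte-like cells.

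Krt20, Sox9 and Hmox1 were highest in the proximal tubule-like class among these 3 classes. Krt20, a keratin of injured tubules, averaged 147 ± 208 CPM there and 1.24 ± 1.44 CPM in thick ascending limb-like cells. Sox9, a transcription factor of tubular repair, averaged 124 ± 135 against 13.4 ± 12.6 CPM, and Hmox1 (heme oxygenase 1) 286 ± 136 against 23.1 ± 10.7 CPM. Cdkn1a (p21) averaged 304 ± 320 against 252 ± 196 CPM, a difference within the spread between mice. Vcam1 and Ccl2 stayed low in both classes, at 17.0 ± 15.2 and 5.72 ± 8.995 CPM in proximal tubule-like and 7.86 ± 8.20 and 3.06 ± 4.50 CPM in thick ascending limb-like cells. T lymphocyte-like cells had 0.947 CPM of Krt20, 2.01 of Sox9, 13.9 of Hmox1, 60.3 of Cdkn1a, 5.06 of Vcam1 and 1.21 of Ccl2. Mouse 3 raised several proximal tubule-like means. Without it Havcr1 averaged 85.8, Lcn2 127, Krt20 43.4, Sox9 57.0, Cdkn1a 144, Vcam1 9.66 and Ccl2 1.28 CPM. In thick ascending limb-like cells the means without mouse 3 were 155 CPM for Cdkn1a, 7.10 for Sox9, 3.86 for Vcam1, 0.850 for Ccl2, 0.525 for Krt20 and 0.214 for Havcr1. In T lymphocyte-like cells they were 25.3 CPM for Cdkn1a, 115 for Lcn2, 0.864 for Sox9, 0.637 for Ccl2 and 0.0496 for Krt20.

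**Figure D2:**
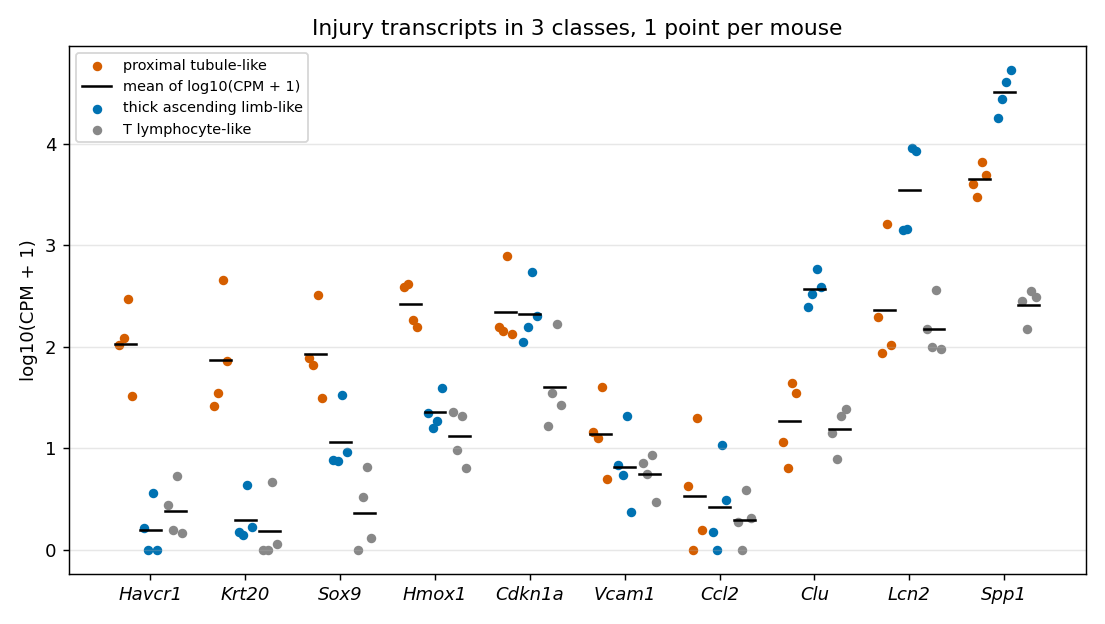
Injury transcripts as log10(CPM + 1) in proximal tubule-like, thick ascending limb-like and T lymphocyte-like cells, with 1 point per mouse and a black bar at the mean of the log values. Havcr1 averages 139 CPM in proximal tubule-like and 0.826 CPM in thick ascending limb-like cells, while Lcn2, Spp1 and Clu are higher in thick ascending limb-like cells.

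Which nephron segment carried more of each stress and metabolic program was asked by comparing proximal tubule-like with thick ascending limb-like cells within each mouse. Higher in the proximal tubule-like class were 6 of 6 gluconeogenesis genes, 4 of 8 endocytosis genes, 9 of 12 NRF2 targets and 5 of 12 antioxidant enzymes, while 1 NRF2 target was lower. The camera calls of these 4 lists were lost, at adjusted p = 0.380 or more with an estimated correlation. Havcr1 and Krt20 were also higher there, whereas Clu, Cd24a and the glycolytic genes Hk1 and Pkm were lower. Of 11871 genes tested, 1494 were higher and 1564 lower in proximal tubule-like cells (edgeR, n = 4 mice, with 394, 181, 787 and 1319 proximal tubule-like and 700, 277, 445 and 487 thick ascending limb-like cells). Thinned to 1000 UMIs per cell, 6274 genes could be tested and 1430 were called.

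All 6 gluconeogenesis genes were higher, as was the case in every leave-one-mouse-out fit. Pck1, the rate-limiting enzyme of the pathway, was at 2971 ± 1519 against 55.996 ± 66.5 CPM (log2 fold change 6.22, SE 0.43), the latter being 23.1 CPM without mouse 2. Of 8 endocytosis genes 4 were higher, among them the receptor Lrp2 (megalin; 6.95, SE 0.37) and Amn (amnionless; 6.80, SE 0.32). Of 12 NRF2 targets, genes of the oxidant response, 9 were higher and 1 lower: Osgin1 (4.16, SE 0.27) and Me1 (4.05, SE 0.23) were higher, and Gclc was lower (-1.52, SE 0.35). Of 12 antioxidant enzymes 5 were higher, led by the secreted peroxidase Gpx3 (7814 ± 1664 against 145 ± 27.2 CPM; 5.74, SE 0.31) and Glrx (3.27, SE 0.42). In camera with the preset correlation the adjusted p was 6.72e-12 for gluconeogenesis, 2.94e-07 for endocytosis, 1.56e-04 for NRF2 targets and 1.13e-03 for antioxidant enzymes. It was adjusted p = 0.380, 0.604, 0.922 and 0.922 with an estimated correlation. Without the mouse block 5 NRF2 targets were higher and 0 lower, and the call of Gclc was lost (adjusted p = 0.147).

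Other metabolic lists were split. Of 14 fatty acid oxidation genes 5 were higher, including Ehhadh (5.36, SE 0.26) and the regulator Ppara (3.51, SE 0.21), and 1 was lower, the coactivator gene Ppargc1a (-1.59, SE 0.27; adjusted p = 0.0833 without the mouse block). The counts were 3 and 2 without mouse 3 and 3 and 0 without the mouse block. Of 11 glycolysis genes 5 were lower, including Hk1 (-4.14, SE 0.36) and Pkm (-3.83, SE 0.33), and 1, Eno1, was higher (1.10, SE 0.20), a call lost without mouse 3 (0.94), after thinning (0.99) and without the mouse block (adjusted p = 0.104). Of 15 oxidative phosphorylation genes 0 were higher and 1 lower, with 4 lower without mouse 3 and 0 without mouse 1, mouse 2 or the block. The 14 hypoxia response genes went both ways, with Adm (4.33, SE 0.53) and Ndrg1 (3.28, SE 0.26) among 3 higher and Pdk1 (-3.10, SE 0.36) and the glucose transporter Slc2a1 (-2.08, SE 0.26) among 4 lower, in counts of 2 and 2 without the block.

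The 16 tubular injury genes also divided between the segments, with 4 higher and 6 lower. Havcr1 (7.15, SE 0.37) and Krt20 (6.56, SE 0.32) were higher in proximal tubule-like cells and Cd24a (-5.12, SE 0.29) and Clu (-4.35, SE 0.36) lower, each in 4 of 4 mice. Of 14 immediate early genes, transcription factors and regulators induced within minutes of stress, 4 were lower, among them Ier3 (-2.40, SE 0.37) and Atf3 (-1.51, SE 0.35). With the injured-marker cluster counted as proximal tubule-like, 1 of the 14 was lower and Atf3 stood at 0.08. Of 11 cell death effectors 5 were higher and 2 lower, with Gsdme (3.45, SE 0.27) and Bid (2.82, SE 0.31) highest, and the counts were 2 and 1 without mouse 3, 3 and 2 without mouse 1, 3 and 1 without mouse 4, and 3 and 0 without the mouse block. Of 6 complement genes 5 were higher, including C3 (3.67, SE 0.34), and the inhibitor Cd59a was lower (-3.18, SE 0.27). Without mouse 3, 3 of 4 tested complement genes were higher. Heat shock genes went both ways (2 higher, 2 lower of 11), the mitochondrial chaperone Hspd1 being higher (1.49, SE 0.24) and the inducible Hspa1b, which has the near-identical copy Hspa1a, lower (-1.55, SE 0.20). Among 10 vasoactive genes the uroguanylin gene Guca2b was higher (6.63, SE 0.31) and the endothelin gene Edn1 lower (-3.21, SE 0.35), in counts of 2 and 3. With the injured-marker cluster counted as proximal tubule-like, Edn1 stood at -0.22 (adjusted p = 0.492). Nos1, known from the macula densa next to the thick limb, had 1 UMI in proximal tubule-like and 291 in thick ascending limb-like cells, a ratio of 240 (95% counting interval 42.8 to 9530).

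Smaller numbers of genes were called in the remaining lists. Inflammatory mediators had 2 higher and 1 lower of 14, the last being Cx3cl1 (-2.87, SE 0.23), matrix and TGF-beta 2 and 1 of 11, MHC class II 2 and 0 of 6, MHC class I 0 and 2 of 8, and p53 targets 2 and 0 of 10. Cell cycle genes had 1 higher and 2 lower of 6, ferroptosis 2 and 0 of 11, interferon response 0 and 1 of 11, and the unfolded protein response 1 and 2 of 12. The MHC class II count was 1 without mouse 1 and 6 of 7 without mouse 2, and that of interferon response genes 2 without mouse 2, 0 without mouse 3 and 3 without mouse 4. MHC class I had 1 lower without mouse 2, ferroptosis 1 higher without mouse 1, cell cycle 1 higher and 0 lower and matrix 3 and 3 without mouse 3, and the unfolded protein response 0 and 1 without mouse 2 or mouse 4. Without the mouse block 1 MHC class II gene, 1 p53 target, 1 inflammatory mediator and 0 genes of MHC class I, ferroptosis, interferon response and the unfolded protein response were called. In 22 of 23 lists the counts were equal when adjusted over the list alone, and the unfolded protein response then had 0 higher and 1 lower. Outside the lists, Calml4 (6.04, SE 0.33) and G6pc1 (5.92, SE 0.35) were among the highest. Gpx6 (-7.88, SE 0.38), Slc16a7 (-6.62, SE 0.30), the calcium-sensing receptor gene Casr (-6.54, SE 0.34), Car15 (-6.37, SE 0.45) and Efhd1 (-5.89, SE 0.24) were among the lowest. Defb42 had 3 UMIs against 936, a ratio of 258 (counting interval 88.0 to 1252). Genes specific to 1 class were also counted at a low level in other classes, which limits how large such ratios can become. The thick limb gene Umod stood at 8802 ± 1569 CPM in its own class, 79.4 ± 30.3 CPM in proximal tubule-like and 62.8 ± 48.3 CPM in T lymphocyte-like cells, and the neutrophil gene S100a9 at 48853 ± 34291, 795 ± 542 and 527 ± 478 CPM in neutrophil-like, proximal tubule-like and T lymphocyte-like cells. The mean of S100a9 in neutrophil-like cells was 31730 CPM without mouse 4, and without mouse 1 the means in T lymphocyte-like cells were 333 CPM for S100a9 and 40.3 CPM for Umod.

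**Figure D3:**
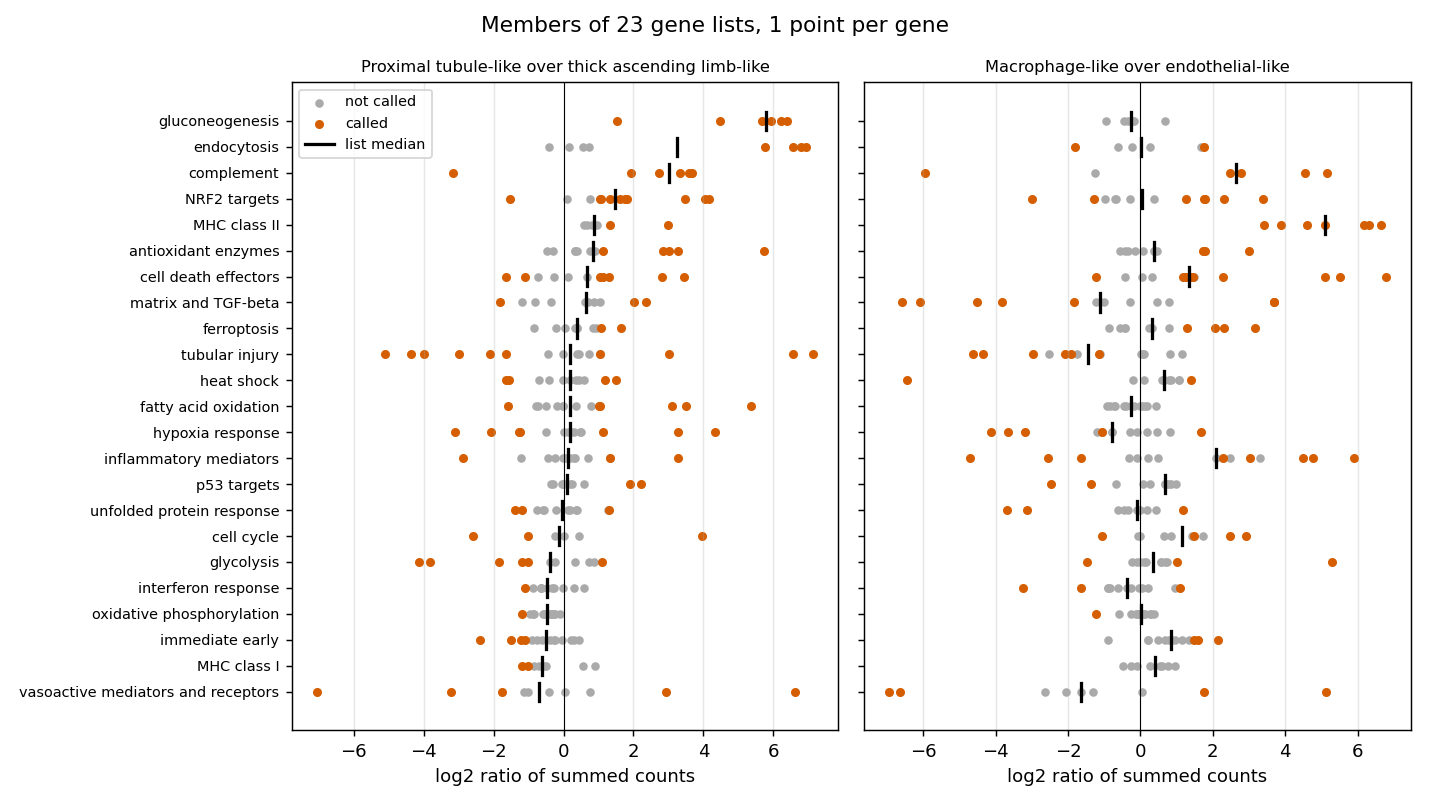
Log2 ratios of the members of 23 gene lists, with 1 point per gene, called genes in orange and a black bar at each list median, for proximal tubule-like over thick ascending limb-like cells and for macrophage-like over endothelial-like cells. All 6 gluconeogenesis genes are called on the left, and all 7 MHC class II genes on the right.

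How cells with injury markers differed from proximal tubule-like cells was asked for the injured-marker cluster, which carries no cell type name. Proximal tubule-like cells carried injury transcripts too, so the comparison was not one of injured with uninjured cells. Sox9, which helped to name the cluster, was not called (121 ± 27.7 against 129 ± 135 CPM; log2 fold change 0.32, SE 0.36; edgeR adjusted p = 0.541). Higher in the cluster were 10 of 14 immediate early genes, 6 of 12 matrix and TGF-beta genes and 7 of 14 inflammatory mediators, with 1 mediator lower. Lower in it were 9 of 12 NRF2 targets, 8 of 14 fatty acid oxidation genes and 4 of 6 gluconeogenesis genes, with 1 gluconeogenesis gene higher. The camera calls of these 6 lists were lost, at adjusted p = 0.320 or more with an estimated correlation. Havcr1, the injury marker of the proximal tubule, was at 2.71 ± 2.68 CPM in the cluster against 143 ± 111 CPM in proximal tubule-like cells (log2 fold change -6.26, SE 0.54), the former being 1.48 CPM without mouse 4 and the latter 89.7 CPM without mouse 3. Genes known from the epithelium of the glomerular capsule moved with these lists: Wt1 (5.78, SE 0.31) and Dkk3 (6.69, SE 0.40) were higher in the cluster, as was Ncam1 (6.76, SE 0.36), while the proximal tubule transporter gene Slc34a1 was lower (-3.07, SE 0.33). Of 10871 genes tested, 1186 were higher and 1138 lower (edgeR, n = 4, with 52, 43, 167 and 75 cells of the cluster in mice 1 to 4). Without the mouse block 1213 genes were called, and after thinning, with 3118 genes tested, 726.

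Of 14 immediate early genes 10 were higher and 0 lower, including the stress factor Atf3 (900 ± 651 against 95.7 ± 25.2 CPM; 3.01, SE 0.40) and Egr1 (712 ± 122 against 90.7 ± 23.5 CPM; 2.99, SE 0.23). The mean of Atf3 in the cluster was 583 CPM without mouse 4. Without the block 6 were higher. Of 12 matrix and TGF-beta genes 6 were higher and 0 lower, led by Tgfb2 (5.46, SE 0.40) and the connective tissue growth factor gene Ccn2 (4.90, SE 0.36); without mouse 4, 4 of 13 were higher. Of 14 inflammatory mediators 7 were higher and 1 lower, among them Csf1 (2.48, SE 0.33) and the chemokine gene Cxcl10 (3.32, SE 0.62). Without the block 3 were higher and the call of Cxcl10 was lost (adjusted p = 0.647). Of 8 MHC class I genes 7 were higher, including Tap2 (1.93, SE 0.20) and H2-K1 (1.88, SE 0.25). Counts of H2 genes are uncertain, since closely similar copies share sequence. This count was 4 without mouse 1 and 3 without mouse 2, and 0 without the mouse block, where Tap2 had an adjusted p of 0.210 and H2-K1 of 0.0693. The camera adjusted p was 9.29e-07 for immediate early genes, 6.57e-04 for matrix, 6.32e-03 for inflammatory mediators and 1.20e-03 for MHC class I. It was adjusted p = 0.369, 0.320, 0.406 and 0.406 with an estimated correlation.

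Of 12 NRF2 targets 9 were lower and 0 higher, including Me1 (-3.75, SE 0.36) and Hmox1 (39.8 ± 15.5 against 304 ± 105 CPM; -2.92, SE 0.21). Adjusted over the list alone, 11 were lower. Of 14 fatty acid oxidation genes 8 were lower, including Ehhadh (-3.24, SE 0.38) and Ppara (-2.94, SE 0.26), and 5 without the block. Of 6 gluconeogenesis genes 4 were lower, with Pck1 (-4.62, SE 0.58) and Pcx (-3.89, SE 0.32) lowest, and Slc37a4 was higher (1.79, SE 0.22). Endocytosis genes had 3 lower of 8, including Cubn (-2.92, SE 0.37) and Dab2 (-2.63, SE 0.25), and 2 without mouse 3. Ferroptosis genes had 3 lower of 11, including Acsl4 (-2.70, SE 0.29), with 2 lower without mouse 2 and 1 without the block. Antioxidant enzymes had 1 higher and 3 lower of 12, with 0 and 5 without mouse 1 and 0 and 2 without the block. Oxidative phosphorylation had 0 and 1 of 15, with 2 lower without mouse 1 or mouse 2 and 0 without mouse 3, mouse 4 or the block. The camera adjusted p was 7.36e-09 for NRF2 targets, 3.10e-06 for fatty acid oxidation, 3.16e-03 for gluconeogenesis, 7.55e-03 for endocytosis, 0.0168 for ferroptosis, 0.0128 for antioxidant enzymes and 9.69e-03 for oxidative phosphorylation. In the same order it was adjusted p = 0.320, 0.369, 0.369, 0.369, 0.369, 0.602 and 0.642 with an estimated correlation.

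Complement genes had 2 higher of 6, C3 at 1296 ± 610 against 119 ± 62.0 CPM (3.51, SE 0.29) and Cd59a (1.10, SE 0.30), whose call was lost without mouse 1 (adjusted p = 0.0676), mouse 2 (adjusted p = 0.107) or the block (adjusted p = 0.345). The camera adjusted p of complement was 0.0452, and adjusted p = 0.406 with an estimated correlation. Vasoactive genes had 4 higher and 2 lower of 10, with Edn1 (4.72, SE 0.33) and the adenosine receptor gene Adora1 (4.55, SE 0.43) highest; adjusted over the list alone, 4 were higher and 4 lower. Heat shock genes had 2 higher and 1 lower of 11 (Hspb1 2.92, SE 0.35), hypoxia response 2 and 2 of 13, glycolysis 2 and 0 of 11 (Hk1 2.74, SE 0.28), and p53 targets 1 and 1 of 11 (Phlda3 3.68, SE 0.36). Interferon response genes had 2 higher of 12, the unfolded protein response 2 of 11, cell cycle 1 of 4, cell death effectors 1 higher and 1 lower of 9, and MHC class II 0 of 7 (edgeR; 1 of 7 at an unadjusted p under 0.05, 0 with DESeq2), with 6 of 7 higher without mouse 4. Interferon response genes had 4 higher without mouse 4, the unfolded protein response 1 without mouse 1 and 0 without mouse 2 or mouse 3, and cell cycle 0 without mouse 2 or mouse 4. Without the mouse block 1 heat shock gene and 0 genes of the interferon response, unfolded protein response, cell cycle and cell death lists were called. The tubular injury list helped to name the cluster and is not a result here; 10 of its 15 genes were higher and 2 lower, Havcr1 and Krt20 (the latter with an adjusted p of 0.0932 without the block; camera adjusted p = 4.56e-06, and adjusted p = 0.369 with an estimated correlation). In 20 of 23 lists the counts were equal when adjusted over the list alone, and matrix and TGF-beta then had 6 higher and 1 lower. Outside the lists, Timp2 (5.97, SE 0.35), Gstm2 (5.92, SE 0.38), Dsp (5.40, SE 0.46) and Bcam (4.92, SE 0.26) were among the highest, and Fbp1 (-3.63, SE 0.44), Cryzl2 (-3.52, SE 0.31) and Adhfe1 (-3.41, SE 0.42) among the lowest.

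Which non-epithelial class carried more of each inflammatory and vascular program was asked by comparing macrophage-like with endothelial-like cells. Higher in macrophage-like cells were 7 of 7 MHC class II genes, which serve antigen presentation, and 8 of 14 cell death effectors, with 1 effector lower. The camera calls of both lists were lost, at adjusted p = 0.997 and 0.923 with an estimated correlation. The basement membrane collagens Col4a1 and Col4a2, the vasoactive genes Ednrb and Nos3, and Hspb1 were higher in endothelial-like cells. Of 12952 genes tested, 2481 were higher and 2096 lower in macrophage-like cells (edgeR, n = 4, with 537, 1065, 2651 and 1642 macrophage-like and 807, 1726, 3578 and 1689 endothelial-like cells). The clusters that made up both classes differed between mice, as given above. The Il27-led cluster of mouse 3 was unnamed in some alternatives and did not enter the macrophage-like sums there. With doublets kept 4294 genes were called, with a mitochondrial limit of 20% 4350, and at the lower clustering resolution 4273.

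All 7 MHC class II genes were higher, including H2-Eb1 (5748 ± 6707 against 46.0 ± 28.8 CPM; 6.66, SE 0.83) and the invariant chain gene Cd74 (6.31, SE 0.98). Mouse 4 had 15708 CPM of H2-Eb1 in macrophage-like cells, and the mean without it was 2427 CPM. Leaving out each mouse gave log2 fold changes of 6.15 to 7.41 for H2-Eb1 and 5.76 to 7.13 for Cd74, each called in every case. H2 genes are uncertain for the reason given above. Of 14 cell death effectors 8 were higher and 1 lower, with the inflammasome genes Il18 (6.77, SE 0.32) and Nlrp3 (5.52, SE 0.38) highest. Adjusted over the list alone 9 were higher and 1 lower, and without the mouse block 5 and 0. The camera adjusted p was 0.0123 for both lists, and adjusted p = 0.997 for MHC class II and 0.923 for cell death effectors with an estimated correlation. Of 15 inflammatory mediators 5 were higher, including Tnf (244 ± 201 against 4.04 ± 2.93 CPM; 5.91, SE 0.42) and Cxcl16 (4.76, SE 0.40), and 3 lower, including Cx3cl1 (-4.69, SE 0.60) and Csf1 (-2.56, SE 0.31). The mean of Tnf in macrophage-like cells was 146 CPM without mouse 4. Without mouse 3, 8 mediators were higher. Complement genes had 4 higher and 1 lower of 6, with C4b (5.14, SE 0.86) higher and Cd59a lower (-5.96, SE 0.57). NRF2 targets had 5 higher and 2 lower of 12, Hmox1 being higher (266 ± 133 against 27.4 ± 19.2 CPM, the latter 17.8 CPM without mouse 3; 3.38, SE 0.19) and Nqo1 lower (-2.99, SE 0.42). Ferroptosis genes had 4 higher of 11, including the ferritin gene Fth1 (3.17, SE 0.33), with 2 higher without mouse 4 and 5 higher and 2 lower without mouse 3. Antioxidant enzymes had 3 higher of 11, led by Glrx (2.99, SE 0.22), with 2 without mouse 4.

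Of 12 matrix and TGF-beta genes 5 were lower in macrophage-like cells, including Col4a1 (14.6 ± 2.57 against 1458 ± 643 CPM; -6.58, SE 0.32) and Col4a2 (-6.08, SE 0.32), and 2 higher, Fn1 (3.68, SE 0.49) and Tgfbr1 (3.68, SE 0.63). Among 9 vasoactive genes the endothelin receptor gene Ednrb (-6.94, SE 0.40) and the nitric oxide synthase gene Nos3 (-6.64, SE 0.21) were lower and the prostaglandin receptor gene Ptger4 higher (5.13, SE 0.54), in counts of 2 lower and 2 higher. Tubular injury genes had 6 lower of 14, led by Sox4 (-4.63, SE 0.31) and Cd24a (-4.34, SE 0.65), and 3 lower without the mouse block. Of 14 hypoxia response genes 4 were lower, including Egln3 (-4.14, SE 0.56) and Adm (-3.65, SE 0.33), and 1, Mxi1, higher (1.68, SE 0.19); adjusted over the list alone, 5 were lower. Of 13 interferon response genes 2 were lower, Ifi44 (-3.25, SE 0.18) and Rsad2 (-1.65, SE 0.19), and 1 was higher. Without mouse 2 or mouse 4, or thinned to 1000 UMIs per cell, 0 were higher, and without mouse 1 or mouse 3, 2 were higher. Without mouse 3 or mouse 4, 3 were lower. Without the mouse block 0 were higher and 1 lower, and Rsad2 had an adjusted p of 0.373. Heat shock genes had 1 higher and 1 lower of 11, the latter being Hspb1 (31.6 ± 25.6 against 3140.5 ± 3276 CPM; -6.44, SE 0.30), with 6 higher without mouse 3 and 0 without mouse 1, mouse 2, mouse 4 or the block. Without mouse 4 the means of Hspb1 were 18.8 and 1507 CPM, and leaving out each mouse gave -6.59 to -6.33.

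Immediate early genes had 3 higher of 14, with 9 without mouse 3 and 1 without mouse 4. Glycolysis genes had 2 higher and 1 lower of 12 (Hk2 5.28, SE 0.57; Hk1 -1.49, SE 0.22), and 1 and 1 adjusted over the list alone. Cell cycle genes had 3 higher and 1 lower of 10, with 2 and 0 without mouse 1 or the block and 1 and 0 without mouse 2 or mouse 4. The unfolded protein response had 1 higher and 2 lower of 11, endocytosis 1 and 1 of 6, p53 targets 0 and 2 of 11, oxidative phosphorylation 0 and 1 of 15. In edgeR, 0 of 13 fatty acid oxidation, 0 of 6 gluconeogenesis and 0 of 8 MHC class I genes were called, with 4, 0 and 4 at an unadjusted p under 0.05 and 0 in each list with DESeq2. Without mouse 3, p53 targets had 3 higher and 1 lower, endocytosis genes 3 and 1, and MHC class I genes 1 and 0. Without mouse 1 or mouse 2, 1 fatty acid oxidation gene was lower, p53 targets had 1 lower without mouse 2 or the block, and the unfolded protein response had 1 lower without the block. In 20 of 23 lists the counts were equal when adjusted over the list alone. Outside the lists, the receptor gene Lilra5 (8.40, SE 0.47), Abca9 (7.95, SE 0.71) and Pou2f2 (7.60, SE 0.46) were among the highest, and Myct1 (-8.25, SE 0.36), Clec14a (-8.13, SE 0.29) and Sox18 (-7.66, SE 0.24) among the lowest.

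Interferon response transcripts stood apart in mouse 3. The 13 genes of the list summed to 4519 CPM in the proximal tubule-like cells of mouse 3 and to 129, 97.5 and 137 CPM in those of mice 1, 2 and 4. In endothelial-like cells the sum was 8668 CPM in mouse 3 against 1384, 1409 and 1615 CPM. Mouse 3 was highest in 13 of 13 classes with 20 cells or more in every mouse, by 4.98- to 36.0-fold over the next mouse.

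**Figure D4:**
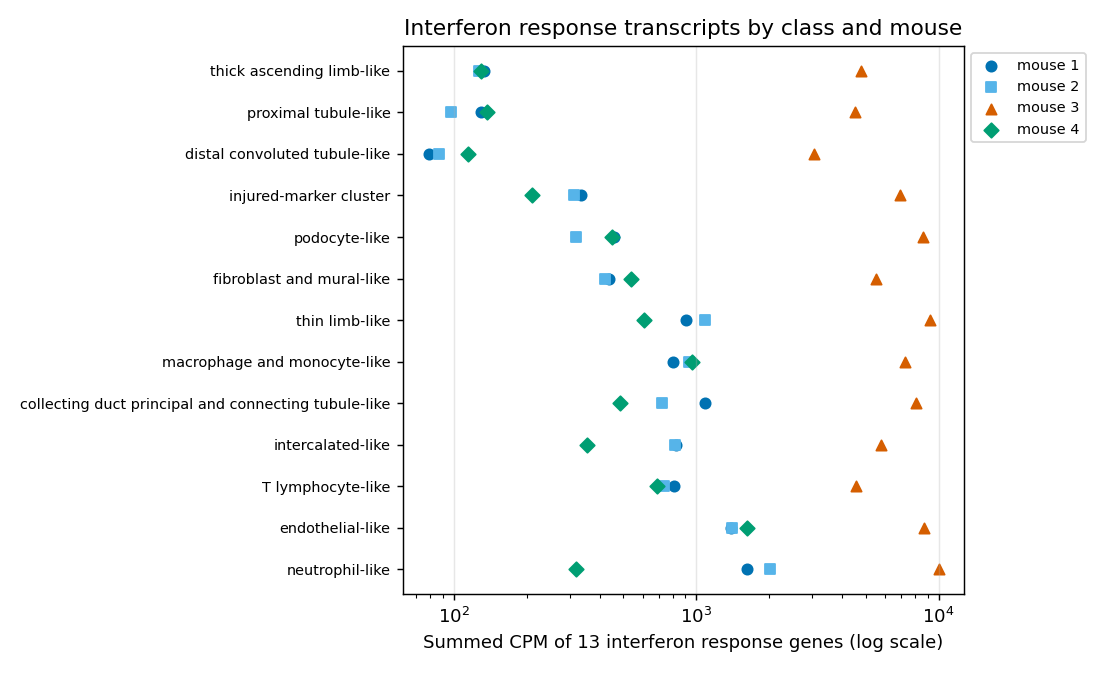
Summed CPM of 13 interferon response genes (log axis) in 13 cell classes, with 1 point per mouse. Mouse 3 is highest in every class shown, from 3049 CPM in distal convoluted tubule-like to 9989 CPM in neutrophil-like cells.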

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

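The comparison of the ribosomal share across classes in mouse 4 was set before its result was seen, and all other tests in this part were chosen after the results they address were seen. Of 59 measures tested for a single mouse far from the other 3 (Dixon's test), 22 passed the 95% limit, where about 2.95 would by chance, at 1 in 20. The flagged values are rounded to 3 digits here, while values set beside them can hold more. The study has 1 group, so no explanation by treatment or another factor of the design was tested for any pattern.

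The library of mouse 4 stood apart in depth and composition, with a median of 2080 UMIs per cell (5549 to 5772 in the others), a ribosomal protein share of 13.7% (1.48% to 2.35%) and a T lymphocyte-like share of 28.3% (3.88% to 4.53%), of which 1238 of 3420 cells lay in cluster 9, led by natural killer receptor genes. Another mix of cell types is argued against for the ribosomal share alone, since it was highest in mouse 4 in 13 of 13 classes, by 2.67- to 7.68-fold over the next mouse. Shallow cells are argued against for T lymphocytes, whose share was 28.4% among cells of 1000 UMIs or more, against 4.32% in the next mouse. The barcodes of mouse 4 differed from those of the other libraries, as it shared 1 barcode with them where 133 were expected. They also began with 960 distinct runs of 6 bases, against 2244 to 2370 in the others. Another barcode set, as from a different chemistry, therefore remains a candidate explanation, and its part in the differences was not tested. How tissue handling or biology contributed stays open.

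In mouse 3, interferon response transcripts reached 4520 CPM in proximal tubule-like cells (97.5 to 137 in the others), 8670 in endothelial-like (1384 to 1615), 7280 in macrophage-like (798 to 962) and 4770 in thick ascending limb-like cells (126 to 133). Free RNA of non-tubular cells is argued against as the source in proximal tubule-like cells, because 20 markers of non-tubular cells stood there at a median 12.4% of their own level where the interferon list stood at 62.5%. Deeper cells are argued against by a median depth 0.999 times that of mice 1 and 2. Mouse 3 shared 96 barcodes with these mice where 92.4 were expected. That expected number was taken in part from the same overlaps, so its closeness to 96 decides nothing about another barcode set. By count, mouse 3 shared 42 and 54 barcodes with mice 1 and 2, while mouse 4 shared 0 and 1 with them. Ren1 stood at 42.8%, so free RNA from some cells stays open for part of the level. Plac8 stood at 114%, which is above its level in the non-tubular cells and so is no measure of free RNA from them. Infection, handling and differences between animals were not tested.

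The injured-marker cluster carried Sox9, Sox4, Dcdc2a, Spp1 and Krt8 with leading genes known from other epithelium. Injured proximal tubule cells high in Havcr1 are argued against, since the log2 ratio of Havcr1 to proximal tubule-like cells was -6.26. Podocyte RNA is argued against by a median of 1.17% of the podocyte-like level over 5 other podocyte markers, the highest of them Synpo at 7.25%, beside Wt1 at 25.1%. Glomerular capsule epithelium may account for the cluster, and 3 of 3 genes tested were higher: Wt1 (5.78), Dkk3 (6.69) and Wnt16, with 416 UMIs against 0, at least 365-fold higher with a floor of 3 counts over the group. This is no independent support, since genes of that epithelium, chosen after the clusters were seen, had also set the cluster apart. Injured tubule cells low in Havcr1 stay open, and the cluster also passed the 2 or more proximal tubule markers that the naming rule asked for.

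Among shares, all under the reported naming of clusters, mouse 3 had 1.13% NK-like cells (0 to 0.0282% in the others). Mouse 4 had 6.41% collecting duct and connecting tubule-like (0.332% to 1.19%) and 4.65% dendritic-like cells (0.0388% to 0.344%). Mouse 1 had 9.88% thick ascending limb-like cells (3.17% to 4.03%). Among cells of 1000 UMIs or more, dendritic-like clusters held 288 and 63 cells of mouse 3, beside 1 cluster with 440 cells of mouse 4. Unnamed cluster 23, led by Umod and Egf, held 164, 35, 372 and 54 cells of mice 1 to 4, which bears on the thick ascending limb-like shares. Summed MHC class I transcripts of mouse 3 reached 11100 CPM in endothelial-like (6314 to 6435) and 4620 CPM in thick ascending limb-like cells (846 to 1019). Its inflammatory mediators reached 6860 CPM in endothelial-like cells (1217 to 1233). Tubular injury transcripts of mouse 3 reached 10900 CPM in endothelial-like (1795 to 3110) and 6860 CPM in macrophage-like cells (806 to 1094). Most of this excess was Lcn2, without which the sums were 2263 CPM (1388 to 2144) and 2772 CPM (768 to 1000.02). Heat shock transcripts of mouse 4 reached 9550 CPM in endothelial-like (3545 to 4083) and 1990 CPM in thick ascending limb-like cells (1166 to 1305). Without Hspb1 these sums were 2193 CPM (2028 to 2329) and 1595 CPM (1134 to 1196). Proximal tubule-like cells of mouse 3 had 783 CPM of Cdkn1a (134 to 157), 457 of Krt20 (24.9 to 71.5), 1610 of Lcn2 (85.0 to 195) and 324 of Sox9 (29.9 to 76.4).

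The 6868 barcodes with a mitochondrial share of 50% or more, which entered no comparison, held proximal tubule S1/S2 marker transcripts at 1180 CPM ± 395 of non-mitochondrial UMIs (SD, n = 4), against 233 ± 50.7 in the barcodes under that limit. The excess was 5.198-, 6.74-, 6.09- and 2.74-fold in mice 1 to 4. Thick ascending limb markers were in excess as well, by 1.91-, 5.16-, 2.48- and 2.49-fold.

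For each comparison, 32 of the 35 ways to split the 8 sums into groups of 4 allowed a fit with the mouse block, and 3 could not be fitted. The real split called 3058 genes for proximal tubule-like against thick ascending limb-like, 2324 for the injured-marker cluster and 4577 for macrophage-like against endothelial-like cells, with 0 as the highest of the others. Both sums of a mouse come from the same animal, so the real split compares only with the 8 splits that part every mouse, of which 1, itself, called as many genes. These are too few for a share under 0.05. The others keep both sums of some mice on 1 side.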

How the results depend on the processing

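The alternatives that took out the highest doublet scores or ribosomal RNA genes or counted the injured-marker cluster as proximal tubule-like were chosen after the data were seen. Of shares, injury transcripts, counts of called genes and camera tests, 460 values stayed on their side of the threshold or within 1.5 times (counts) or 1 SD between mice (shares and transcripts), 9 moved and 19 lost significance. With 4 mice, leaving out 1 cannot move a mean by 1 SD, so shares and transcripts without a mouse were bound to count as stayed. Krt20 in proximal tubule-like cells, for example, went from 147 to 43.4 CPM without mouse 3. The mean distal convoluted tubule-like share was 2.97% with centring within library (1.82% in the reported setting), and the thin limb-like share 0.707% with the highest doublet scores out and 0.967% at 1000 UMIs or more (0.474%). The unnamed share was 6.51% with the highest doublet scores out (13.6%). Some shares stayed within their wide spread between mice but moved by over 1.5 times. The NK-like share was 0.815% with a mitochondrial limit of 20% and 0 with centring or at resolution 0.5 (0.296%), and the dendritic-like share was 0 at resolution 0.5 (1.29%). No cluster earned the name where a share was 0. The cause of these moves was not tested. The macrophage-like share of mouse 3 depended on naming as well. Its Il27-led cluster, with 1387 cells, was unnamed with doublets kept, with a mitochondrial limit of 20% and at resolution 0.5. The shares of mice 1 and 2 depended on naming too, since unnamed cluster 13 held macrophage and neutrophil markers in 781 and 272 of their cells. Thinning to 1000 UMIs left fewer genes to test, and 1430 were called for proximal tubule-like against thick ascending limb-like cells (3058) and 726 for the injured-marker cluster (2324). Without the replicate block the latter count was 1213, and the other counts of called genes stayed within 1.5 times. Thinned, Ccl2 stood at 3.59 CPM in T lymphocyte-like (1.21) and Havcr1 at 2.498 CPM in thick ascending limb-like cells (0.826), near the level of single UMIs.

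With an estimated correlation no camera call held. The adjusted p became 0.380 for gluconeogenesis, 0.604 for endocytosis and 0.922 for NRF2 targets and antioxidant enzymes in proximal tubule-like against thick ascending limb-like cells. In the injured-marker cluster it became 0.320 for NRF2 targets and matrix, 0.369 for immediate early, fatty acid oxidation, gluconeogenesis, endocytosis, ferroptosis and tubular injury, 0.406 for complement, inflammatory mediators and MHC class I, 0.602 for antioxidant enzymes and 0.642 for oxidative phosphorylation. In macrophage-like against endothelial-like cells it became 0.923 for cell death effectors and 0.997 for MHC class II.

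Of the named genes, 2 turned direction. In proximal tubule-like against thick ascending limb-like cells, Atf3 went from -1.51 to 0.0826 with the injured-marker cluster counted as proximal tubule-like, which carries more Atf3, and Slc7a11 from 1.07 to -0.0638 with the highest doublet scores out, whose cause was not tested. Across all settings 74, 48 and 75 pairs of gene and setting lost the call in the 3 comparisons and 1089, 901 and 950 stayed on the same side of the threshold. The fit without the replicate block accounted for 56 of the losses.

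Leaving out each mouse gave 2826 to 3363, 2020 to 2473 and 3644 to 5076 called genes. The injured-marker cluster had 43 cells in mouse 2. In simulated data 10% to 52% of 2-fold changes were recovered at an adjusted p under 0.05 without the fold limit. Changes of this size can therefore be missed in each comparison.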

Other observations

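No test was added in this part, and the values below were picked after they were seen. Several injury transcripts were higher in other classes than in the proximal tubule. Cdkn1a (p21, a brake on the cell cycle) averaged 1281 ± 858 CPM in endothelial-like cells (SD, n = 4), 715 ± 664 CPM in podocyte-like and 304 ± 320 CPM in proximal tubule-like cells. Lcn2 averaged 10154 ± 7981 CPM in thin limb-like and 9129 ± 4639 CPM in collecting duct and connecting tubule-like cells. Neutrophil-like cells, which store its product in granules, had 10517 ± 12215 CPM, and 4421 CPM without mouse 3. Clu averaged 2866 ± 3395 CPM in collecting duct and connecting tubule-like and 2504 ± 1767 CPM in distal convoluted tubule-like cells. Spp1 averaged 29437 ± 5146 CPM in distal convoluted tubule-like and 28114 ± 18159 CPM in intercalated-like cells. Vcam1 averaged 292 ± 214 CPM in macrophage-like and 273 ± 356 CPM in endothelial-like cells. Without mouse 3 the mean of Vcam1 in endothelial-like cells was 95.6 CPM, that of Cdkn1a 390 CPM in podocyte-like and 144 CPM in proximal tubule-like cells, and that of Clu 1204 CPM in collecting duct and connecting tubule-like and 1661 CPM in distal convoluted tubule-like cells.

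The clusters of proximal tubule-like cells differed in injury transcripts within a mouse. Havcr1 stood at 134, 185 and 51.6 CPM in cluster 14 of mice 1, 2 and 4 and at 51.8, 19.4 and 19.3 CPM in cluster 11 of the same mice. Hmox1 ran the other way, at 292, 343 and 93.5 CPM in cluster 14 and 517, 500.5 and 196 CPM in cluster 11. So did Krt20, at 10.8, 14.5 and 50.9 CPM in cluster 14 and 54.3, 65.6 and 84.3 CPM in cluster 11. Sox9 went both ways, at 58.9, 55.1 and 44.1 CPM in cluster 14 and 112, 85.0 and 21.2 CPM in cluster 11. Some of these values rest on few positive cells, and counting error was not computed for them. Havcr1 was found in 7.14% of the 84 cells of cluster 11 in mouse 2. Krt20 was found in 2.83% of 212 and 6.74% of 89 cells of cluster 14 in mice 1 and 2. In mouse 3, cluster 27 had 161 CPM of Havcr1, 615 of Krt20 and 439 of Sox9, and cluster 14 had 498, 230.3 and 157 CPM.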
